A study of Mus musculus with 3008 samples.

How the data were processed

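Single-cell RNA sequencing by inDrops, a method that captures single cells in droplets with barcoded primers, was read for Foxp3+ regulatory T cells (Tregs) from the spleen and the colon lamina propria of male mice aged 7 months. Per the labels' protocols, the mice carried a Foxp3-Ires-Gfp reporter on the B6 background, spleens were dissociated mechanically and colons were digested with collagenase and dispase, and live DAPI- TCRb+ CD4+ GFP+ cells were sorted. The protocols give oligo-dT reverse transcription in the droplets, linear amplification by in vitro transcription, and sequencing on a NextSeq500. The submitters' processing notes name TopHat2, SAMtools and the mm10 build of the mouse genome without versions or parameters. The step each tool was used for, the annotation, the collapsing of unique molecular identifiers (UMIs) and the choice of cells are not given in the sources used here.

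The deposited table holds 1 count of UMIs per gene and cell for 23725 genes, of which 7983 had no UMI in any cell. The values were whole numbers, and each library's cells summed to 98.4%, 98.2% and 98.2% of the UMI numbers in the labels of spleen, colon 1 and colon 2. Every column of the table was matched to a labelled cell, and 0 columns were left out. The table of cell labels that accompanies the counts carried no cell type and was not used here. Gene positions come from the GENCODE vM21 annotation of the same build.

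Cells were grouped by library and tissue as the labels give them, which makes 1 spleen library and 2 colon libraries. The title of the second colon library calls it a second replicate, while its sample type carries the number of the first, and the labels name no animal. Each tissue was therefore treated as 1 sample, the colon libraries are shown apart, and no p-value or standard error across animals was computed from cells. UMI counts were summed over the cells of a library and scaled to counts per 1000000 UMIs (CPM) over all genes. Each colon library was divided by the spleen library, with a 95% exact conditional binomial interval for the ratio, exact Poisson intervals for CPM and exact Clopper-Pearson intervals for shares of cells. These intervals cover counting error only. Intervals for the digestion genes, the colon-low genes and Ccr7 in colon cells that clustered with spleen cells were also made by drawing cells 10000 times with replacement, and cover the spread between cells of these libraries only. A gene with 0 UMIs in a library was set to a floor of 3 counts. The ratio is then a bound at that floor, and the end of its 95% interval can lie closer to no difference.

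Genes with at least 50 CPM in the spleen library or in both colon libraries were eligible for the gene counts, and a ratio of 2 in both colon libraries in the same direction was the threshold. Genes were named by a rule. It takes the 15 highest and the 15 lowest eligible genes by the smaller of both log2 ratios in size, leaving out T cell receptor, immunoglobulin, mitochondrial and ribosomal protein genes and unnamed gene models. It adds Foxp3, Il2ra, Ctla4, Ikzf2, Gata3, Il1rl1, Il10, Ccr7, Klf2, Fos, Hspa1a, Cd4 and Cd8a in every case, up to 4 members of each gene list with the largest mean log2 ratio in size, and the 10 genes with the highest fold in each cluster. A few further genes are named as chosen after their values were seen. Some genes that the rule names, and the gene list and comparison that rest on them, are not reported here.

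The gene lists were Treg identity, resting lymphoid-organ T cell, activated effector Treg, suppressive and repair effectors, GATA3-ST2-Helios Treg, trafficking receptors, TCR-induced early genes, TNFR and NF-kB, dissociation and heat-shock response, interferon response, cell cycle, glycolysis and MHC class I. Lists for other cell types covered B cells, plasma cells, macrophages or dendritic cells, granulocytes or mast cells, colon epithelium, stroma or endothelium, erythroid cells or platelets, CD8 or NK cells and conventional helper T cells. A member was measured with at least 30 UMIs over the 3 libraries. The median log2 ratio of a list was placed among 10000 random lists of the same size drawn from 20 expression bins with a fixed seed, which describes these libraries and is no test across animals.

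For clustering, cells were scaled to 10000 UMIs and log-transformed in scanpy 1.11.5, and 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.8 (igraph 0.11.9) were used without batch correction. Shares of cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs, which left out 4, 9 and 28 shallower cells of spleen, colon 1 and colon 2. The groups, gene lists, naming rule, comparisons and the alternatives from the list below were fixed before the data were examined, except where the text says otherwise.

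The alternatives were edgeR 4.0.16 TMM scaling in R 4.3.3, median of ratios scaling, totals without ribosomal protein genes (the table held no mitochondrial genes), equal weight per cell, thinning, removal of cells with 2 markers of another cell type, of doublets called by Scrublet, or of cells above the 98th percentile of UMIs, leaving out each colon library, no CPM minimum or one of 100, other Leiden resolutions, 1000 variable genes, clustering without the dissociation and heat-shock genes, and thinning to 800 or 1500 UMIs or none. A pair of alternatives was added after seeing the data: removing the colon cells of the cluster with the highest Fosb, Hspa1a, Hspa1b and Atf3, and removing the colon cells in clusters made mostly of spleen cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

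The procedure was tested on simulated data. Of 100 genes changed 4-fold in both simulated colon libraries, 100% passed the ratio of 2, against 1% of 100 genes changed 1.5-fold, and the intervals held the true ratio for 97.5% and 96.5% of them. With no gene changed, 0 of 3249 genes passed in either direction although both ratios share the spleen library, but the simulation held counting error alone and no difference between animals or preparations. In a simulated mixture of 800 cells from 2 populations, 100% of cells fell in a cluster of their own population, but the procedure drew 4 clusters, with an adjusted Rand index of 0.764. It therefore splits a uniform population further than the simulation warrants.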

Results

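The transcripts of single Foxp3+ regulatory T cells (Tregs), the CD4+ T cells that restrain immune responses, were counted in cells sorted from the spleen and from the colon lamina propria, the connective tissue under the gut epithelium. Spleen cells made 1 library of 617 cells, and colon cells made 2 libraries of 619 and 1772 cells, called colon 1 and colon 2. The summed counts of unique molecular identifiers (UMIs) were 1255946 in spleen, 1253246 in colon 1 and 3916649 in colon 2. The median cell held 1847, 1767 and 2026.5 UMIs and 758, 756 and 875 genes in that order. Per the labels, spleen was dissociated mechanically and colon by enzymes, so that tissue and dissociation cannot be told apart. The labels name no animal, so whether the colon libraries come from separate mice is not known. The intervals are 95% intervals of counting error, and both colon ratios share the same spleen library.

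The comparison of colon with spleen asks how Tregs of the gut wall differ from those of a lymphoid organ. Colon Tregs held far more transcripts of secreted and cytotoxic effectors. Gzmb, which encodes the protease granzyme B (chromosome 14, 56258838 to 56262260, minus strand, mm10), stood at 41.4 CPM (UMIs of a gene per 1000000 UMIs of its library) in spleen, 2647 in colon 1 and 2659 in colon 2, and Il10, the gene of an anti-inflammatory cytokine (chromosome 1, 131019845 to 131024974, plus strand), at 43.0, 1361 and 1499.5 CPM. Spleen Tregs held more transcripts of many genes of circulating, resting T cells. Igfbp4, which encodes a binding protein of insulin-like growth factors (chromosome 11, 99041244 to 99054392, plus strand), was 18.2 and 17.5 times lower in colon 1 and colon 2 than in spleen, and Tcf7, the gene of a transcription factor of resting and memory-like T cells, 5.21 and 11 times lower.

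The log2 ratio of Gzmb was 6.0 (5.60 to 6.42) in colon 1 and 6.01 (5.61 to 6.43) in colon 2, and that of Il10 was 4.98 (4.59 to 5.40) and 5.12 (4.74 to 5.54). Without cells holding 2 markers of another cell type, the mean log2 ratio of Gzmb was 6.61, above both of its intervals. The intervals take UMIs as independent and leave out the spread between cells. In spleen, the 52 UMIs of Gzmb lay in 13 of 617 cells and the 54 UMIs of Il10 in 15. Among 3482 genes with at least 50 CPM in a tissue, 409 were at least 2-fold higher in both colon libraries than in spleen and 155 at least 2-fold lower. At 4-fold these counts were 168 and 24. Leaving colon 1 out gave 563 and 270 genes and leaving colon 2 out gave 475 and 241; of the higher genes, 63 and 34 were eligible only in that setting, and of the lower genes 0. Totals without ribosomal protein genes, which took 28.5% of spleen UMIs and 17.6% and 16.3% of colon UMIs, gave 348 higher and 351 lower genes and moved the median log2 ratio of all eligible genes from 0.02 to -0.24.

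Among the 15 genes with the highest ratios, Fosl2, which encodes a subunit of the AP-1 transcription factor (chromosome 5, 32135801 to 32157842, plus strand), was 164-fold and 188-fold higher in colon 1 and colon 2, from 4.78 CPM in spleen. Lmna, the gene of the nuclear envelope proteins lamin A and C (chromosome 3, 88480147 to 88509956, minus strand), was 158-fold and 196-fold higher. Crem, which encodes a transcription factor that answers cyclic AMP, stood at 23.1 CPM in spleen and 1415 and 1505 CPM in colon. Cdkn1a, the gene of the cell cycle inhibitor p21, was 65.9-fold and 86.2-fold higher, and Ramp3, which encodes a partner protein of peptide hormone receptors, 63.9-fold and 89.9-fold. Fosl2, Lmna, Cdkn1a and Ramp3 rested on 6, 7, 5 and 5 spleen UMIs. In that order, their log2 intervals in colon 1 were 6.23 to 8.81, 6.25 to 8.62, 4.81 to 7.68 and 4.76 to 7.63. Dusp14, which encodes a phosphatase of signalling kinases, had 0 spleen UMIs. With the floor of 3 counts it was 35.4-fold and 35.7-fold higher, with lower log2 interval ends of 4.82 and 4.85. Some ratios rested on 1 to 3 spleen UMIs, as for Cxcr6, a chemokine receptor gene of tissue T cells, with a log2 ratio of 7.07 (4.57 to 12.38) and 6.97 (4.48 to 12.27). The others of this kind were Mmp9, at 6.42 (4.86 to 8.71) and 6.56 (5.01 to 8.84), Mt2, at 6.45 (3.93 to 11.77) and 6.17 (3.68 to 11.48), Pqlc1, at 6.08 (4.2 to 9.14) and 6.49 (4.63 to 9.54), Gbp2b, at 6.03 (3.5 to 11.35) and 5.98 (3.49 to 11.29), and Ccr1, at 5.57 (3.68 to 8.64) and 5.68 (3.81 to 8.73).

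At the other end, next to Igfbp4, Nrn1, the gene of the membrane-anchored protein neuritin, was 20 and 13.6 times lower in colon 1 and colon 2, and Id3, which encodes an inhibitor of E protein transcription factors, 17.9 and 11 times. Nrp1, the gene of a surface receptor found on many thymus-derived Tregs, was 7.83 and 6.39 times lower, and Cd7, a gene of a T and NK cell surface protein, 9.48 and 15.8 times. Further genes of the 15 lowest, Usp18, Evl, Nsg2, Slfn1, Treml2, Ifit1bl1, Sh2d3c and Ift80, were between 5.29 and 28.5 times lower in either library.

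**Figure D1:**
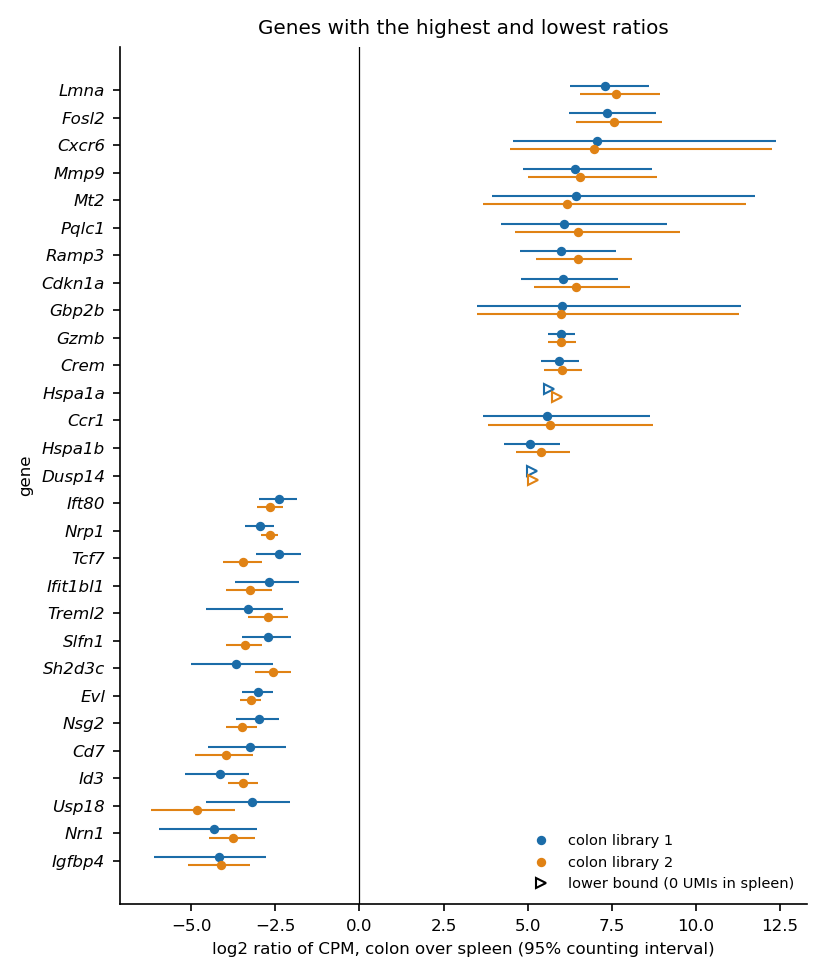
The log2 ratio of CPM, colon over spleen, is drawn on the horizontal axis for the 15 highest and 14 of the 15 lowest genes, with 1 point per colon library and bars for the 95% counting interval; open triangles are lower bounds for genes with 0 spleen UMIs. Gzmb lies at 6.0 and 6.01, and the bars of Cxcr6, with 1 spleen UMI, run from 4.57 to 12.38 in colon 1. The bars take UMIs as independent and leave out the spread between cells.

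Genes that define Tregs went in both directions. Foxp3, the lineage transcription factor, stood at 282 CPM in spleen, 452 in colon 1 and 306 in colon 2, and its log2 ratio in colon 2 was 0.12 (-0.05 to 0.29). Ikzf2, which encodes the transcription factor Helios, was 1.25 and 1.24 times lower in colon, and Gata3, a transcription factor gene of type 2 and tissue-repair programs, 1.70-fold and 1.67-fold higher. Il2ra, the gene of the high-affinity interleukin-2 receptor chain, was 1.79-fold and 2.48-fold higher, and Cd4 2.09-fold and 2.96-fold. Klf2, a transcription factor gene that keeps T cells circulating, was 1.87 and 1.86 times lower, and Fos, an early gene of the AP-1 family, stood at 217, 202 and 225 CPM with intervals of both ratios that included 0. Cd8a had 2, 0 and 1 UMIs.

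The gene lists show which programs these genes belonged to. In the activated effector Treg list, 14 of 17 measured genes were at least 2-fold higher in both colon libraries and 0 lower, with Icos, a costimulatory receptor gene, 8.23-fold and 12.5-fold higher and Id2, an inhibitor of E proteins, 9.60-fold and 9.27-fold. Of the suppressive and repair effectors, 8 of 10 were higher and 0 lower, among them Lag3, an inhibitory receptor gene, at 13.1-fold and 11.6-fold, and Fgl2, which encodes a secreted suppressive protein, at 8.21-fold and 11-fold. In the resting lymphoid-organ list, 10 of 14 were lower and 1 was higher, Il7r, a receptor chain gene named after its value was seen, at 2.13-fold and 2.14-fold. Ccr7, a chemokine receptor gene of that list, was 1.80-fold and 1.91-fold higher, short of 2-fold. Dapl1, also of that list, had 31 spleen UMIs and 0 colon UMIs. With the floor of 3 counts it was 10.3 and 32.2 times lower, with upper log2 interval ends of -2.98 and -4.63. In the Treg identity list, 5 of 14 were higher, with Tnfrsf9, a costimulatory receptor gene, 6.17-fold and 7.45-fold and Ctla4, the gene of an inhibitory receptor, 5.49-fold and 4.68-fold, and 4 were lower, with Nrp1 among them.

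Most markers of a colon Treg subset were higher as well. In the GATA3-ST2-Helios list, 5 of 8 genes were higher and 1, Nrp1, lower. Il1rl1, which encodes ST2, the receptor of the alarm cytokine interleukin-33, was 10.4-fold and 8.40-fold higher. Areg, the gene of the repair factor amphiregulin, was 9.61-fold and 7.10-fold higher. Of the genes that name the list, Gata3 was 1.70-fold and 1.67-fold higher and Ikzf2 1.25 and 1.24 times lower, short of 2-fold. The ratio of Rora rested on 3 spleen UMIs. Il10, Areg, Nrp1, Ikzf2 and several receptor genes belong to more than 1 list, so that the lists are not independent. Of the trafficking receptors, 10 of 18 were higher and 3 lower, with Ccr8, a chemokine receptor gene of tissue Tregs, at 2 spleen UMIs and a log2 ratio of 3.76 (1.77 to 6.88) and 3.31 (1.40 to 6.39).

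The lists for signalling moved along with these. Of the TCR-induced early genes, 5 of 10 were higher and 1 lower: Irf4, a transcription factor gene of effector Tregs, was 8.77-fold and 9.20-fold higher, and Egr2, an early growth response gene, 6.32 and 2.65 times lower. Of the TNFR and NF-kB list, 8 of 12 were higher and 0 lower, with Tnfrsf1b, the gene of TNF receptor 2, 4.50-fold and 6.08-fold and Traf1, an adaptor gene of these receptors, 3.06-fold and 4.02-fold. Of the dissociation and heat-shock list, 9 of 19 were higher and 1 lower. Fosb, an AP-1 gene, was 22.4-fold and 24.4-fold higher, and Hspa1b, a heat-shock protein gene, 33.6-fold and 42.0-fold. Hspa1a, with 0 spleen UMIs set to the floor, was 49.8-fold and 59.0-fold higher, with lower log2 interval ends of 5.32 and 5.58. The lower gene was Zfp36, an RNA decay factor named after its value was seen, at 2.73 and 2.27 times lower. Enzyme digestion is known to induce genes of this list, and they were higher in the same libraries as the effector genes.

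The remaining lists were interferon response, cell cycle, glycolysis and MHC class I. Of the interferon response list, 0 of 12 were higher and 3 lower, with Usp18, a brake of interferon signalling, 9.12 and 28.5 times lower and Rtp4 4.2 and 3.08 times. Of the cell cycle list, 5 of 12 were higher and 0 lower: Pcna, a replication clamp gene, was 3.08-fold and 3.38-fold higher, while Mki67, a marker gene of dividing cells named after its value was seen, stood at 25.5, 21.5 and 17.6 CPM. Of the glycolysis list, 2 of 9 were higher, among them Aldoa, an enzyme of the pathway, at 2.57-fold and 3.03-fold. Of the MHC class I list, 0 of 10 passed 2-fold in either direction. H2-K1, a classical antigen-presenting gene, was 1.68-fold higher in each colon library.

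Each list was set against 10000 random lists of matched expression. The median log2 ratio in colon 1 and colon 2 was 1.67 and 1.46 for activated effector, 2.93 and 2.89 for suppressive and repair and 2.34 and 2.58 for GATA3-ST2-Helios genes, all above every random list. It was -2.23 and -1.73 for resting lymphoid-organ genes, below every random list, and -0.72 and -0.75 for interferon response genes, at percentiles 0.08 and 0.09. The medians of the trafficking (1.11 and 1.22), TCR-induced (1.09 and 1.2), TNFR and NF-kB (1.35 and 1.21) and dissociation and heat-shock lists (0.82 and 1.27) lay above the percentile 99.8, and those of the cell cycle (1.05 and 0.74), glycolysis (0.88 and 1.09) and Treg identity lists (0.76 and 0.74) between 98.3 and 99.9. The MHC class I median, 0.10 and 0.11, lay at percentiles 38.4 and 43.7, and the median over its genes of the mean of both ratios turned to -0.11 with totals without ribosomal protein genes. A percentile describes these libraries and not other mice.

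**Figure D2:**
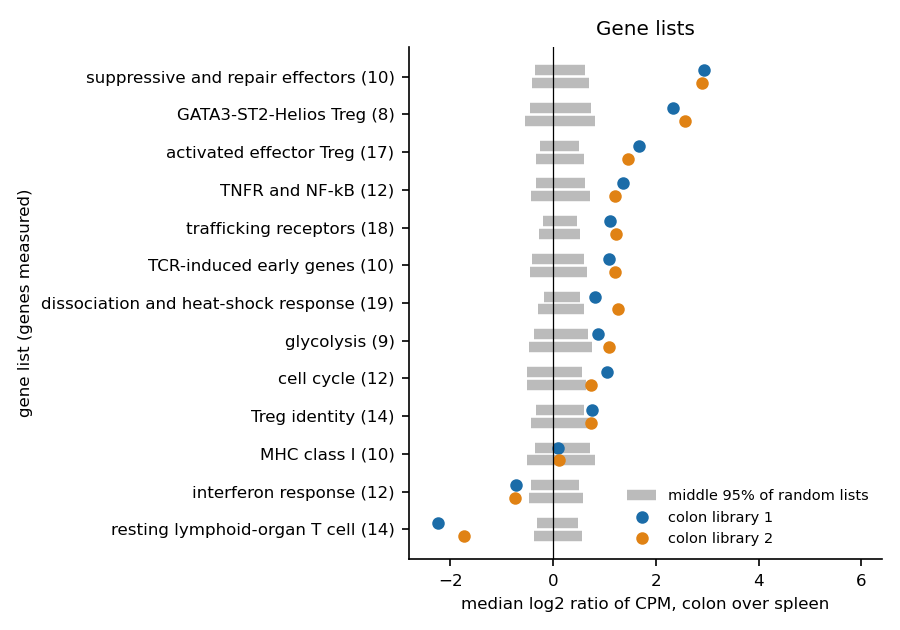
The median log2 ratio of CPM, colon over spleen, is drawn for each gene list with the number of genes measured, with 1 point per colon library and grey bars for the middle 95% of random lists. The resting lymphoid-organ list lies at -2.23 and -1.73, left of its grey bar, and the MHC class I list, at 0.10 and 0.11, lies inside it.

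In each list for other cell types, most members fell short of 30 UMIs over the 3 libraries or were not in the table. Of the B cell list, 3 of 14 genes were measured and 2 were at least 2-fold higher in both colon libraries, H2-Eb1 with 1 spleen UMI and a log2 ratio of 4.59 (1.97 to 9.95) and 4.51 (1.98 to 9.83) and H2-Aa with 2 spleen UMIs and 1.81 (-0.58 to 5.11) and 3.63 (1.72 to 6.70). All 11 genes of the list that the table holds summed to 84.4 CPM in spleen and 73.4 and 110 CPM in colon. Of the plasma cell list, 1 of 3 was higher, Jchain, an antibody joining chain gene, with 0 spleen UMIs and 11.2 and 4.85 CPM in colon, and Xbp1, a transcription factor gene of secretory cells, stood at 60.5, 109 and 169 CPM. Of the macrophage or dendritic cell list 1 of 2 was higher, Apoe, with 0 spleen UMIs and 7.18 and 16.3 CPM, while Cst3, the gene of a protease inhibitor, stood at 102, 221 and 199 CPM. Of the granulocyte or mast cell list, 1 of 1 was higher, Ccr3, at 7.17, 24.7 and 16.1 CPM. Of the colon epithelium list, 0 of 3 were higher and 1 was lower, Lgals4, at 3.99 and 4.16 times. The stroma or endothelium list had 0 of 2 past 2-fold, with Pecam1, an adhesion protein gene, at 101, 53.5 and 51.1 CPM, the conventional helper list 0 of 4, and the erythroid or platelet list 0 measured genes. In the CD8 or NK list of 4, Nkg7, a cytotoxic granule gene, was 5.51-fold and 3.85-fold higher and Ccl5, a chemokine gene, 4.57 and 6.71 times lower, from 113 CPM in spleen; Cd8b1 stood at 63.7, 50.3 and 41.6 CPM.

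The colon libraries give the one repeat in the design. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.959 between colon 1 and colon 2, against 0.761 and 0.726 between spleen and each of them, with Spearman values of 0.931, 0.700 and 0.664. The log2 ratio of colon 2 to colon 1 had a standard deviation of 0.43 over eligible genes, and the ratios of colon 1 and colon 2 to spleen 1.05 and 1.12. At least 2-fold differences between the colon libraries were found for 84 genes, 59 of them higher in colon 1, and spleen was nearer to colon 1 for 61. Rpl26, a ribosomal protein gene, stood at 176 CPM in spleen, 101 in colon 1 and 2.30 in colon 2, and Ubb, a ubiquitin gene, at 216, 582 and 103 CPM; both were chosen after their values were seen. Spleen and colon 1 had a median of 58.7 and 61.6 reads per UMI and colon 2 had 26.7, and no sequencing batch is labelled. Spleen and colon 1 are the pair alike in reads per UMI, and the ratios of colon 1 are the values within it.

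Clustering of all cells gave 6 clusters. Of the spleen cells, 99.4% (98.3 to 99.8%) fell in clusters 0 and 1, and 4.36% (2.89 to 6.28%) of colon 1 and 2.03% (1.43 to 2.80%) of colon 2 cells joined them. Cluster 0 (534 cells) carried resting lymphoid-organ markers, 8 of 11 detected markers being at least 2-fold higher than in the other cells and Id3 and Nsg2 among its 10 top genes. Cluster 1 (142 cells) was set apart by Itgb1, an integrin gene, and Trat1, a gene of a T cell receptor-associated protein. Colon cells filled clusters 2 to 5, where spleen gave 3, 1, 0 and 0 cells. These top genes and markers define the clusters and are no separate finding.

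Among the colon clusters, cluster 3 (780 cells) carried GATA3-ST2-Helios markers, with 6 of 8 at least 2-fold higher than in all other cells. Il1rl1 and Penk, the gene of the opioid precursor proenkephalin, were among its top genes. All other cells include the spleen cells, so marker counts and top genes of clusters 2 to 5 can hold part of the tissue difference. Within colon, Gata3 stood in cluster 3 at 1234 CPM in colon 1 and 1129 in colon 2, against 166 and 110 in cluster 4. Cluster 2 (275 cells) was topped by Hey1, Ccr7, the gene of a lymph node homing chemokine receptor, and Bcl6, the master transcription factor gene of follicular T cells. Of its 11 detected resting lymphoid-organ markers, 5 were at least 2-fold higher than in all other cells, with a median log2 fold of 0.97. Its 14 detected activated effector markers had a median of -1.26, with 1 at least 2-fold higher. Cluster 4 (772 cells) had Laptm4b, Tmem176b and Csf1 among its top genes. Cluster 5 (505 cells) had 4 dissociation and heat-shock genes, Hspa1a, Fosb, Hspa1b and Klf6, among its top 10.

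Effector transcripts differed between these colon clusters, for genes chosen after their values were seen, except Il10 and Gzmb. None of these genes was barred from the clustering, which used the same cells. Their differences can thus follow from how the clusters were drawn and are no separate finding. Il10 stood at 131 and 98.2 CPM in cluster 2 of colon 1 and colon 2, at 1288 and 1414 in cluster 3, at 1538 and 1877 in cluster 4 and at 2241 and 1915 in cluster 5. Gzmb was at 111 and 39.7 CPM in cluster 2, at 3804 and 3432 in cluster 3, at 2127 and 1986 in cluster 4 and at 3936 and 4249 in cluster 5. Klrg1, a gene of a receptor of differentiated T cells, stood at 1609 and 2055 CPM in cluster 3, against 39.3 and 112 in cluster 2, 253 and 263 in cluster 4 and 468 and 712 in cluster 5. Between clusters 3 and 4 Lag3 showed the opposite order, with 131 and 97.6 CPM in cluster 3 and 316 and 332 in cluster 4. Ikzf2 was at 864 and 783 CPM in cluster 2, at 884 and 990 in cluster 3, at 385 and 331 in cluster 4 and at 423 and 372 in cluster 5. The borders of the clusters are not stable: between 4 and 10 clusters were drawn under other settings, and 43 of 50 shares of cells left their interval. The share of colon 1 cells in the cluster with the highest Il1rl1 was 30.4% (26.8 to 34.2%) and went as low as 7.11%, so no claim rests on the size of a cluster.

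**Figure D3:**
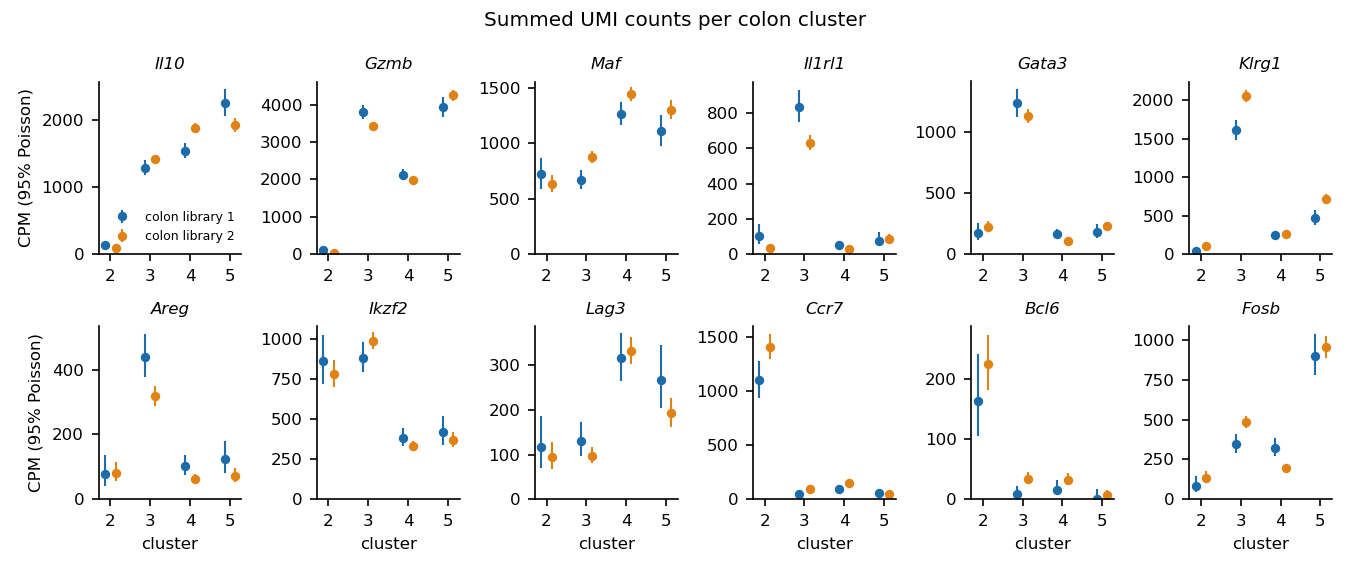
CPM of summed UMI counts is drawn per gene for the colon clusters 2 to 5, with 1 point per colon library and bars for the 95% Poisson interval; each vertical axis starts at 0. Cluster 3 has the highest Gata3, at 1234 and 1129 CPM, and cluster 2 the lowest Il10, at 131 and 98.2 CPM. The clusters were drawn from the same cells, and these genes were not barred from the clustering.

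The share of cells with a UMI, at an equal depth of 1000 UMIs per cell, shows how widely a transcript was found. Il10 was seen in 1.47% (0.673 to 2.77%) of spleen cells and in 50.2% (46.1 to 54.2%) of colon 1 and 49.1% (46.8 to 51.5%) of colon 2 cells. Gzmb was seen in 1.47%, 47.7% and 47.6%, and Icos in 17.1%, 76.6% and 85.0%. Il1rl1 reached 2.61%, 15.4% and 13.8%, and Areg 1.79%, 12.1% and 10.6%. Klf2 went the other way, with 33.6%, 18.9% and 19.2%.

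Foxp3 was seen in 20.2% (17.1 to 23.6%), 32.0% (28.3 to 35.8%) and 25.2% (23.2 to 27.3%) of cells that were sorted by its reporter, so that a cell without a UMI is not a cell without the transcript. Gata3, at 20.7%, 24.4% and 23.7%, and Ikzf2, at 36.2%, 32.5% and 32.9%, had overlapping intervals. Ccr7 was found in 10.6%, 9.84% and 8.72% of cells, while its CPM was 135 in spleen and 244 and 259 in colon, where cluster 2 held 1100 and 1407 CPM. Free RNA also gives low shares of cells with a UMI, and the libraries hold no other cell type to measure it. Jchain, which Tregs do not make, was seen in 0.492% (0.102 to 1.43%) of colon 1 and 0.688% (0.356 to 1.2%) of colon 2 cells. Epcam, an epithelial gene, was seen in 2.77% of spleen, 1.64% of colon 1 and 4.01% of colon 2 cells. Since spleen cells held it too, Epcam gives no measure of free RNA from the colon epithelium. Shares of this size were not read as shares of expressing cells.

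**Figure D4:**
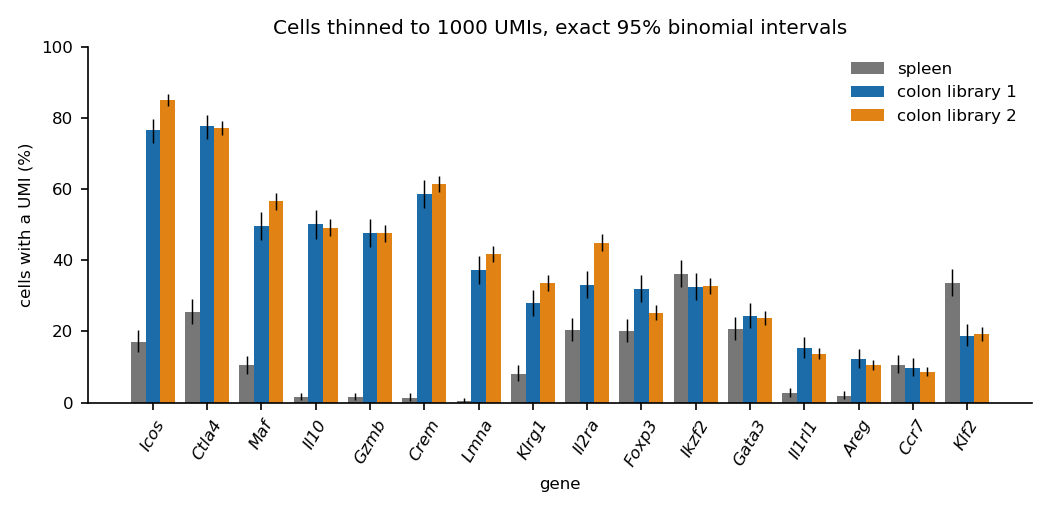
The percent of cells with at least 1 UMI of each gene is drawn for spleen, colon 1 and colon 2 after thinning each cell to 1000 UMIs, with exact 95% binomial intervals. Il10 and Gzmb stand at 1.47% in spleen and between 47.6% and 50.2% in colon, and Klf2 at 33.6% in spleen and 18.9% and 19.2% in colon.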

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

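The removal of the colon cells of the cluster with the highest Fosb, Hspa1a, Hspa1b and Atf3, and of the colon cells in clusters made mostly of spleen cells, were chosen only after the results were seen; all other alternatives were planned. A named gene counts as moved when its log2 ratio left the span of both colon libraries' counting intervals. This span is wider than either interval and has no upper end for Hspa1a and Dusp14. A share of cells counts as moved when it left its interval, and a count of genes when it changed by over 1.5 times. A list median counts as moved when it shifted by more than the standard deviation between the colon libraries. Of 560 named-gene values 551 stayed within the span of both libraries' intervals and 0 whose span excluded 0 turned direction. Of 28 gene counts 21 stayed within 1.5 times. The 40 named-gene values without a CPM minimum and the 40 with one of 100 could not move, since it sets only which genes are eligible. List medians could not move there either. The 40 values for each left-out colon library could not move, since the other library's ratio lies in its own interval. The gene counts over the scaling and cell-removal alternatives not named below ran from 398 to 420 higher and from 136 to 172 lower, against 409 and 155. No paired analysis was possible because the groups share fewer than 2 replicate numbers, and no alternative could separate tissue from digestion.

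Some counts moved. Without a CPM minimum 992 genes were higher and 517 lower, and with a minimum of 100 CPM 256 and 71, since more or fewer genes could pass. Totals without ribosomal protein genes gave 351 lower genes. Both the ratios and the set of eligible genes change there: the 3482 genes of the main analysis gave 247 lower genes, against 155, and 910 newly eligible genes gave 104. The median log2 ratio of all eligible genes fell to -0.24. Leaving out a colon library gave 241 to 270 lower genes, all of them eligible in the main analysis, because a gene then had to pass in 1 library. Among named genes, the mean log2 ratio of Gzmb went to 6.61 without cells with 2 markers of another cell type, and thinning to 1000 UMIs left Cxcr6 without a spleen UMI, so that its 4.44 is a lower bound. The lower bounds of Hspa1a and Dusp14 became 4.81 and 4.09 with thinning, and that of Hspa1a 5.06 without the cells of the cluster with the highest Fosb, where Fos went to -0.51 from -0.03. With totals without ribosomal protein genes, Gata3 went to 0.54 from 0.75, Klf2 to -1.11 from -0.90 and Ikzf2 to -0.54 from -0.32.

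The gene list values here are medians over genes of the mean log2 ratio of both colon libraries, which can differ from the medians of each library. With totals without ribosomal protein genes, MHC class I turned from 0.10 to -0.11, Treg identity moved to 0.58 from 0.80, activated effector to 1.31 from 1.52, suppressive and repair to 2.75 from 2.97, GATA3-ST2-Helios to 2.32 from 2.53, trafficking to 0.95 from 1.17, TCR-induced to 0.93 from 1.15, TNFR and NF-kB to 1.10 from 1.32, interferon response to -0.77 from -0.56 and glycolysis to 0.80 from 1.02. With TMM and median of ratios scaling, Treg identity was 0.83 and 0.84, suppressive and repair 3.0 and 3.01, interferon response -0.53 and -0.51 and MHC class I 0.13 and 0.15. With equal weight per cell, GATA3-ST2-Helios was 2.35, interferon response -0.60 and MHC class I 0.086. Thinned to 1000 UMIs, Treg identity was 0.81, GATA3-ST2-Helios 2.32, TCR-induced 1.38, interferon response -0.77, cell cycle 0.67 and MHC class I 0.091. Without doublets, Treg identity was 0.81 and suppressive and repair 2.92, and without cells above the 98th percentile the latter was 2.88. Leaving out a colon library leaves the median of a single library, a different statistic, which gave 0.74 to 0.76 for Treg identity, 2.89 to 2.93 for suppressive and repair, 2.34 to 2.58 for GATA3-ST2-Helios, 1.21 to 1.35 for TNFR and NF-kB and -0.75 to -0.72 for interferon response. Without the cells of the cluster with the highest Fosb, Treg identity was 0.77, suppressive and repair 3.12 and TCR-induced 0.98, and without colon cells in clusters of mostly spleen cells suppressive and repair was 3.0. Apart from MHC class I, no list median changed sign under the alternatives run. The cause of these shifts was not tested, except that another total moves all genes alike.

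Shares of colon cells in clusters depended on the settings. At resolution 0.5 they were 2.99% of colon 2 for the clusters of mostly spleen cells, 25.5% of colon 1 and 30.6% of colon 2 for the cluster with the highest Il1rl1, 13.6% of colon 2 for Bcl6, and 55.7% and 52.8% for the cluster with both the highest Lag3 and the highest Fosb, Hspa1a, Hspa1b and Atf3 (the stress genes). At resolution 1.2 they were 2.93% of colon 2 for mostly spleen, 14.2% and 17.6% for Il1rl1, 9.85% and 8.24% for Bcl6, 8.72% and 5.53% for Lag3 and 4.2% and 4.18% for stress genes. With 1000 variable genes they were 9.05% and 4.68% for mostly spleen, 15.3% and 14.9% for Il1rl1, 7.92% and 7.73% for Bcl6, 21.5% and 20.3% for Lag3 and 4.36% and 6.15% for stress genes. Without dissociation and heat-shock genes among the variable genes they were 2.88% of colon 2 for mostly spleen, 7.11% and 6.77% for the cluster with both the highest Il1rl1 and the highest stress genes, 8.40% and 7.90% for Bcl6 and 23.6% and 25% for Lag3. Thinned to 1000 UMIs they were 2.92% of colon 2 for mostly spleen, 21.8% and 21.2% for Bcl6, and 41.5% and 40.5% for the cluster with both the highest Lag3 and stress genes. The cause was not tested beyond the number of clusters, which was 4 to 10.

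Depth limits the shares of cells with a UMI: 139 of 243 left their interval when the depth was changed.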

Other observations

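The tests of digestion, of ribosomal dilution, of ribosomal depth and of the Itgb1-high spleen cells, the tests of unchanged spleen cells, and the checks with cells drawn again and on all 406 genes, were chosen only after the results were seen; the tests of shared barcodes and of mixed material were not.

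Spleen Tregs were not uniform. With the genes that differ 2-fold between tissues left out of the clustering, 7 clusters of spleen cells were drawn, and the one with the most Itgb1, an integrin gene, held 144 cells, or 23.3% of spleen, at 750.04 against 188 CPM in the other spleen cells. S100a4 and S100a6, chosen after their values were seen and genes of calcium-binding proteins of activated and migrating cells, stood there at 1970 against 218 CPM and at 3125 against 394 CPM. Gzmb stood at 100.01 against 17.9 CPM, and Klrg1, also chosen after its value was seen, at 425 against 93.8 CPM. The 52 Gzmb UMIs of spleen lay in 13 of 617 cells, so the Gzmb contrast rests on few cells. Without cells with 2 markers of another cell type, the mean log2 ratio of Gzmb, colon over spleen, was 6.61 against 6.0. Il10 stood at 94.5 against 22.3 CPM, but in the clustering of all cells spleen cells of cluster 1, with high Itgb1, held 42.8 CPM (22.8 to 73.2) and those of cluster 0 40.4 CPM (28.6 to 55.4). A hypothesis was that these spleen cells hold part of the colon profile. Itgb1, by which the cluster was picked, was itself lower in colon. It stood at 349 CPM over all spleen cells. In colon cells outside the clusters of mostly spleen cells it stood at 51.3 CPM in colon 1 and 62.4 CPM in colon 2. The 285 genes higher in colon that were measured had a median log2 ratio 0.20 above that of other genes, 178 of them above it, and the genes lower in colon -0.26. This excess lies between the bounds set for the test, 0.5 for and 0.2 against, so the hypothesis stays undecided.

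A few colon cells, 27 of colon 1 and 36 of colon 2, clustered with spleen cells. Cell barcodes shared between libraries do not account for them, since 0% of the 27 carried a spleen cell's barcode, which allows up to 12.8%, against 0.845% of the other 592 colon 1 cells. Spleen cells mixed in after the digestion would lack the genes that digestion induces. Fosb, Hspa1a, Hspa1b and Atf3 together stood at 360 CPM (259 to 489) in these cells, at 760 CPM (527 to 1063) in those of colon 1 and 101 CPM (40.7 to 209) in those of colon 2, against 28.7 CPM in spleen. The bound set for the test was a counting interval above 2 times the spleen value. It took UMIs as independent, but 7 of the 63 cells held all 41 UMIs and one of them 25. With cells drawn again with replacement the interval was 41.0 to 906 CPM, which includes the bound, so the test decides nothing. By cells, 11.1% (4.59 to 21.6%) of the 63 held a UMI of the 4 genes, against 2.27% (1.25 to 3.78%) of spleen cells. In the other cells of colon 1 and colon 2 the share was 35.5% and 41.2%. Free RNA of colon cells could raise this share as well, so it does not settle the question. Other genes argue against unchanged spleen cells as the whole of these cells. They do not exclude it, since the 155 genes used were picked from these same libraries and Ccr7 is 1 gene. The 155 genes at least 2-fold lower in colon took 2.12% (1.74 to 2.56%) of their UMIs in colon 1 and 2.45% (2.15 to 2.78%) in colon 2, with cells drawn again, against 3.62% (3.55 to 3.69%) in spleen. Free RNA of colon cells would lower this too, but not raise Ccr7 to 1543 CPM (492 to 3067) and 839 CPM (346 to 1460), against 135 CPM in spleen and 196 and 248 CPM in the other cells of colon 1 and colon 2. Spleen cells as a part of these cells, or mixed in before the digestion, stay open, as do resting-like Tregs that belong to the colon, which were not tested.

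The high expression of colon-high genes could come from the enzymes used on colon alone, and tissue and digestion cannot be told apart by design. In cluster 2, which had the least of the 4 digestion genes, the 13 named colon-high genes had a median log2 ratio that was 60.4% of that in cluster 5, with the most, in colon 1 and 65.1% in colon 2, while the digestion genes lay 3.24 and 2.37 lower on the log2 scale in that order. Over all 406 colon-high genes measured it was 81.3% and 82.6%. Of these, 272 and 287 were at least 2-fold above spleen in cluster 2, and 334 and 362 in cluster 5. Both gene sets were picked from these same libraries for being higher in colon, so a high percentage is partly built in. The values of the 13 named genes lie between the bounds set for the test, 50% and 75%, and clusters differ in cell type as well. Digestion as a source of part of the difference therefore stays open. A difference between the tissues themselves stays open too and was not tested.

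Ribosomal protein genes took a median of 28.1% of UMIs per spleen cell, against 16.9% in colon 1 and 15.5% in colon 2. A few genes that take many counts in colon would dilute all others alike, but the median log2 ratio of ribosomal protein genes lay at -0.76 in colon 1 and -0.88 in colon 2 relative to the other eligible genes, which excludes such dilution as the whole cause. Depth per cell is excluded as well: in cells of 1500 to 2500 UMIs the medians were 29.2%, 16.8% and 15.3%, and the difference of colon 1 from spleen was 111% of that over all cells. Spleen cells of cluster 1 held 21.0% and those of cluster 0 30.7%, and colon clusters 2 to 5 between 14.8% and 19.3%. Tissue and digestion stay open and were not tested for this pattern.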
